A study of Mus musculus with 18 samples.

How the data were processed

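RNA was measured in 18 libraries of mouse bone marrow-derived mast cells, from 2 genotypes (WT, Sirt6 alleles flanked by loxP; KO, the same with Cre from the lysozyme M promoter) at 3 levels (0, 20 and 60), with 3 libraries per group. Per the labels, marrow was flushed from femurs and tibias and cultured, and mRNA libraries were made from total RNA with a TruSeq kit. The strand of the libraries is not stated. The submitters' processing notes name bcl2fastq 2.20.0, FastQC 0.11.7, HISAT2 2.1.0 for alignment to mm10 and StringTie 2.1.3b for quantification.

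The authors deposited a single table of 45777 genes with 3 values per library. Per the file headers these are a read count per gene, which the authors did not normalize, an FPKM and a TPM. All 54 value columns were mapped to libraries, and 99.8% of the gene IDs were found in the RefSeq annotation of GRCm38 used for positions and biotypes. The counts were analysed, and the deposited FPKM and TPM values were used as alternatives. Total counts per library ran from 20026054 to 42265435, and a count of 3 in the smallest library is 0.150 CPM. For a group with 0 counts a bound on the fold was computed with 3 counts over the whole group.

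Genes were kept by filterByExpr, which left 17159, and counts were scaled with TMM factors. A quasi-likelihood model with 1 mean per group was fitted to all 18 libraries in edgeR 4.0.16 under R 4.3.3. It gave 10 comparisons: KO against WT at each level and over all levels, 20 and 60 against 0 in each genotype, and the difference between the genotypes in each response. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. CPM use TMM-scaled library sizes, and means and SD are over 3 libraries, or over 3 cultures for all levels. Principal components used log2 CPM with a prior count of 2. Single genes were tested with an exact permutation test of the mean log2(CPM + 0.1), whose 20 splits of 6 libraries give a smallest two-sided p of 0.1.

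The comparisons, the 29 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. Named genes are called genes with a symbol and a mean of at least 5 CPM in a compared group: the 12 largest rises and 12 largest falls per comparison, 8 and 8 over all levels, and 6 and 6 for differences in response. With under 5 calls, the 5 smallest p are given as values. For each list 2 to 4 members are named, and Sirt6 and Lyz2 always. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with adjustment over the lists of a comparison. Each list was tested again with an estimated correlation, with fry, with the replicate number as a block, and on the compared groups alone. A list call counts as held when it passes with the estimated correlation.

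The replicate number was judged to pair a comparison by the log2 values of the paired libraries after removal of the group means. These had to correlate above 0.1 in all 3 numbers. This was so for KO against WT at 60 (0.43 to 0.53), WT 20 (0.62 to 0.76), KO 20 (0.40 to 0.58) and KO 60 (0.33 to 0.67). The main fit used no block in any comparison, so its calls ignore this pairing. With the block these comparisons had 183, 158, 105 and 1094 calls, against 46, 103, 77 and 436 without it. The correlation within a culture was estimated at 0.447. The first principal component held 29.3% of the variance and correlated with the log2 mitochondrial share at −0.873. The mitochondrial share was computed over 15 genes, and alternatives with this share were added after the data were seen.

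Alternatives were DESeq2 1.42.0, limma-voom with and without the culture as a random effect, other scalings and filters, protein-coding genes only, the compared groups only, the replicate number as a block, sums per culture, TPM and FPKM, stricter thresholds, and each library or number left out. Scaling by library size alone shifted the median of all genes by 0.16 for KO against WT at 0, by 0.16 at 20, by 0.11 over all levels, by −0.22 for KO 60 against 0 and by −0.14 for the difference in response at 60. Clustering of called genes was measured as the share with another called gene within 5 Mb, against 1000 random sets drawn from 20 bins of expression. Libraries of a group were checked for copies of one another, and none were found. Tables were read with the R package data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9.

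The analysis was tested on simulated data: negative binomial counts for 17159 genes with 1 mean per gene, the dispersions estimated per gene from all 18 libraries and the real library sizes, in which 200 genes of at least 5 CPM were changed in KO at 0. It recovered 28.6% of 70 genes changed 2-fold, 86.3% of 73 changed 4-fold and 98.2% of 57 changed 8-fold, with 4 false calls among 143. In simulated data without changes edgeR called 0 genes in each of the 10 comparisons, with 4.59% to 5.36% of genes at an unadjusted p under 0.05. The simulated libraries were independent of one another, so these counts do not cover the correlation within a culture and say nothing about false calls over all levels. Raising the glycolysis list 2-fold gave it an adjusted p of 5.4e-28 in camera, and 1 other list was called.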

Results

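Gene expression was measured by RNA-seq in mouse bone marrow-derived mast cells, which are grown from marrow in culture and are a standard model of tissue mast cells. The WT cells carried Sirt6 alleles flanked by loxP sites, and the KO cells carried in addition Cre recombinase expressed from the lysozyme M promoter, which is active in myeloid cells. Sirt6 encodes a nuclear NAD-dependent deacetylase. Each genotype was sampled at 3 levels, 0, 20 and 60, whose unit the labels do not give. The labels name no treatment at 0 and lipopolysaccharide (LPS), a bacterial ligand of the receptor TLR4, at 20 and 60, whereas the series title names FcεRI, the IgE receptor of mast cells. Each of the 6 groups held 3 libraries, numbered 4120, 414 and 6110 in every group, so that there were 18 libraries. The labels do not say whether these numbers are separate animals or cultures, so p-values measure only the spread between these samples, part of which may be technical. Sex-linked transcripts set number 414 apart from the other 2, so its cells came from at least one other animal. Libraries of one number and one genotype at the 3 levels are called a culture here. Total counts per library ran from 20026054 to 42265435, and any bound that rests on a count of 0 covers counting error only.

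Genes encoded in mitochondrial DNA took very different shares of the counts, from 4.07% in one KO library at 0 to 41.7% in one WT library at 60. The mean share in WT was 22.6% ± 14.5 at 0, 17.4% ± 14.3 at 20 and 22.1% ± 17.4 at 60 (SD, n = 3). In KO it was 13.7% ± 11.9 at 0, 6.32% ± 1.61 at 20 and 14.4% ± 17.4 at 60. The ranges of KO and WT overlapped at every level, although within the numbers KO had the lower share in 7 of 9 pairs, including all 3 at 60 (4.45% against 8.80%, 34.5% against 41.7% and 4.27% against 15.7%). The 2 pairs with the higher share in KO were number 414 at 0 (27.0% against 17.7%) and at 20 (8.17% against 6.53%), and 5 of the 18 libraries had a share over 20%.

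**Figure D1:**
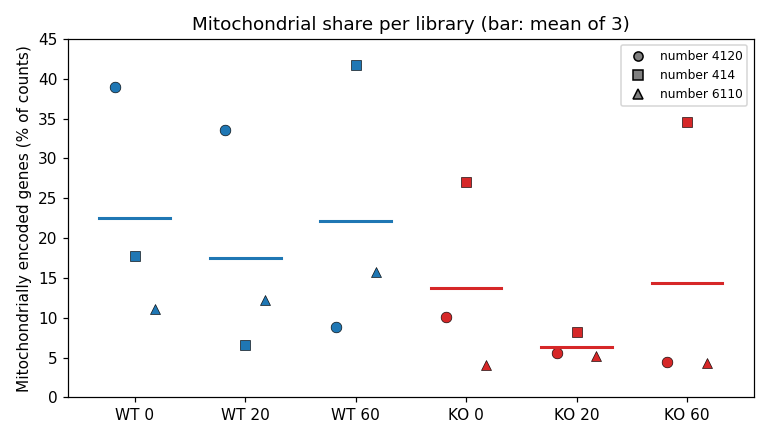
Share of counts taken by mitochondrially encoded genes in each library (percent of total counts), by genotype and level, with a horizontal bar at the mean of 3 libraries and the marker shape giving the library's number. The 5 libraries over 20% are WT 0 and WT 20 of number 4120, WT 60, KO 0 and KO 60 of number 414, and the KO libraries at 20 lie between 5.24% and 8.17%.

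The targeted gene was examined first. Sirt6 (gene ID 50721, chromosome 10, 81621787 to 81627792 in GRCm38) was counted at 16.7 ± 2.66 CPM in KO and 14.6 ± 2.44 CPM in WT at 0 (SD, n = 3). At 20 it was 17.1 ± 3.47 in KO and 14.7 ± 3.50 in WT, and at 60 it was 11.8 ± 1.72 in KO and 10.7 ± 1.02 in WT. Two-sided exact permutation tests gave p = 0.4, 0.6 and 0.5 at 0, 20 and 60, and edgeR gave log2 fold changes of 0.19, 0.22 and 0.14 with Benjamini-Hochberg adjusted p of 0.74, 0.79 and 0.85. Counts are given per gene and the deleted exons are not given in the sources used here, so reads from the rest of the transcript are included and Sirt6 checks no genotype label. The counts also do not show whether, or in what share of the KO cells, Sirt6 was deleted. Without number 4120 the Sirt6 difference at 0 was −0.017. Lyz2 encodes lysozyme M, at whose locus the Cre of this line is inserted (gene ID 17105, chromosome 10, 117277541 to 117282272). It had 9, 10 and 6 counts over the 3 KO libraries at 0, 20 and 60, against 156, 172 and 186 counts in WT. The exact permutation test gave p = 0.1 at each level, the smallest that 3 against 3 libraries allow, and the edgeR adjusted p was 0.10, 0.17 and 0.086. Over all levels Lyz2 fell by 4.48 on the log2 scale in KO (edgeR adjusted p = 0.00035). That test counts the 3 levels of a culture as separate samples, and Lyz2 did not pass with counts summed per culture.

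The first question of the design was which transcripts differ between KO and WT in untreated cells. In KO at 0, several transcripts that were well expressed in WT were nearly missing. Gbp2b, an interferon-inducible GTPase (chromosome 3, 142594816 to 142619179), was counted at 7.43 ± 5.69 CPM in WT and had no count in KO, at least 276-fold lower (SD, n = 3). Add2, the beta subunit of the membrane skeleton protein adducin, fell from 112 ± 21.1 CPM in WT to 3.49 ± 2.47 CPM in KO, and the kinase-like receptor gene Styk1 fell from 277 ± 173 to 15.0 ± 3.56 CPM. Col6a3, a chain of collagen VI (chromosome 1, 90766860 to 90844001), rose from 1.73 ± 0.846 CPM in WT to 131 ± 84.7 CPM in KO, and the potassium channel gene Kcnh6 rose from 1.26 ± 0.818 to 22.1 ± 11.6 CPM. Nxpe2, which overlaps Nxpe4 in the annotation, rose from 0.209 ± 0.254 to 10.5 ± 3.31 CPM. The other named rises on the log2 scale were Gm9008 (3.26), Hmgn1 (3.24), Clba1 (2.07), Gm15459 (1.85), Rabif (1.79), Tanc2 (1.48), the BMP receptor gene Bmpr1a (1.19), Sh3d19 (1.18) and Dcaf7 (1.02). The other named falls were Gm42048 (−9.05), Gm9522 (−8.89), Gm10154 (−8.13), Gm5900 (−7.04), Rpl34-ps1 (−6.84), Rps3a3 (−6.77), Gm4705 (−5.65), Nectin1 (−5.42) and Gm5586 (−3.12). Gm9008, Gm15459, Gm9522, Gm10154, Gm5900, Rps3a3, Gm4705 and Gm5586 are annotated as pseudogenes, and Rpl34-ps1 is named as one. Their values are uncertain because reads can be shared with parent genes, as are those of Hmgn1 and Gbp2b, which have close copies, and of Nectin1, which overlaps Gm46108. Itgam, an integrin of macrophages and neutrophils, had 101 counts in KO and 3 in WT and passed the test (edgeR adjusted p = 0.033). It was not called at 20 (1.28, edgeR adjusted p = 0.65), at 60 (2.23, edgeR adjusted p = 0.29) or with counts summed per culture. All 11 tested markers of neutrophils and granulocyte precursors, of 16 on the list, had positive log2 fold changes, with a median of 3.18. Levels were low, such as 0.594 ± 0.256 CPM in KO for Lcn2. In WT Ltf and Ly6g had no count, and Lcn2, Ngp, S100a8 and S100a9 had means of 0.022, 0.075, 0.16 and 0.28 CPM. Markers this low in WT could pass filterByExpr through their counts in KO, which favours positive values. The shared sign and the test of this list are thus not independent evidence of a rise. In that list 0 members passed edgeR over all genes and 3 passed adjusted over the list alone, and the list test gave adjusted p = 1.9e-05, against adjusted p = 0.56 with an estimated correlation. Of the 27 genes of cholesterol synthesis 26 had positive log2 fold changes with a median of 0.46, 0 passed over all genes and 2 passed adjusted over the list alone, among them Hsd17b7 (2.11) and Stard4 (1.04). The cholesterol list had adjusted p = 1.2e-07, against adjusted p = 0.56 with an estimated correlation. The mitochondrial share was 13.7% ± 11.9 in these KO libraries and 22.6% ± 14.5 in WT. At an adjusted p of 0.05, edgeR called 47 of 17159 genes, 17 higher and 30 lower in KO. The count was 27 without KO 0 of number 414, 29 without KO 0 of number 6110 and 30 without WT 0 of number 4120, and DESeq2 called 251.

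At 20, Gbp2b, Add2, Styk1 and Col6a3 again differed between KO and WT. Gbp2b was counted at 8.27 ± 4.14 CPM in WT and had no count in KO, at least 262-fold lower (SD, n = 3). Add2 fell from 159 ± 77.4 to 4.52 ± 1.74 CPM, Styk1 from 238 ± 113 to 9.05 ± 1.78 CPM and the cell adhesion gene Nectin1 from 13.7 ± 2.02 to 0.126 ± 0.0486 CPM. Col6a3 rose from 1.58 ± 0.916 to 111 ± 77.8 CPM, Kcnh6 from 1.41 ± 0.168 to 16.9 ± 3.42 CPM, and Kpna2, a nuclear import adaptor with an annotated pseudogene copy, from 7.87 ± 0.669 to 24.5 ± 7.87 CPM. The other named rises were Nxpe2 (5.61), Gm9008 (3.33), Hmgn1 (2.68), Clba1 (1.85), Rabif (1.53) and Tanc2 (1.47). The other named falls were Gm42048 (−9.55), Gm9522 (−8.78), Gm10154 (−8.08), Gm5900 (−6.77), Rpl34-ps1 (−6.22), Rps3a3 (−6.15), Gm4705 (−6.01) and Gm5586 (−3.16). The expression filter favoured positive values in the list of neutrophil and granulocyte precursor markers, as in untreated cells. All 11 markers of neutrophils and granulocyte precursors again had positive log2 fold changes, with a median of 2.72. In edgeR 0 of them passed over all genes and 1 passed adjusted over the list alone, with a list adjusted p of 8.3e-06, against adjusted p = 0.35 with an estimated correlation. All 27 genes of cholesterol synthesis had positive values with a median of 0.29, 0 passed over all genes and 1 passed adjusted over the list alone. That list had adjusted p = 1.3e-05, against adjusted p = 0.76 with an estimated correlation. For glycolysis 19 of 23 genes had positive values with a median of 0.49, and 0 passed either way. The glycolysis list had adjusted p = 0.0022, against adjusted p = 0.76 with an estimated correlation, and it lost its call when the mitochondrial share, 6.32% ± 1.61 in KO and 17.4% ± 14.3 in WT, was a covariate. By edgeR at an adjusted p of 0.05, the test called 36 genes, 10 higher and 26 lower in KO. The count was 22 without any one of the KO 20 libraries of numbers 4120, 414 and 6110, and DESeq2 called 119.

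At 60, among called genes with a mean of at least 5 CPM in KO or WT, the largest differences were those of Col6a3, which rose from 1.36 ± 0.289 CPM in WT to 128 ± 98.7 CPM in KO, and of Gm42048, which fell from 261 ± 95.9 to 0.477 ± 0.217 CPM (SD, n = 3). Gbp2b fell from 8.86 ± 3.83 to 0.0790 ± 0.0738 CPM, Add2 from 171 ± 25.3 to 5.73 ± 2.05 CPM and Styk1 from 209 ± 97.7 to 5.48 ± 0.395 CPM. Kpna2 rose from 10.6 ± 1.52 to 48.7 ± 16.6 CPM, and Got1, the cytosolic aspartate aminotransferase, rose from 38.1 ± 2.73 to 72.8 ± 8.04 CPM. The other named rises were Kcnh6 (3.97), Gm9008 (3.40), Hmgn1 (3.24), Gm15459 (1.96), Clba1 (1.79) and Tanc2 (1.61). The other named falls were Gm9522 (−8.28), Gm10154 (−7.43), the inhibitory lectin receptor gene Clec12b (−6.88), Rps3a3 (−6.39), Gm5900 (−6.31), Gm4705 (−6.27), Rpl34-ps1 (−6.25) and Nectin1 (−5.60). The annotation of Clec12b overlaps other lectin genes, and its value is uncertain. In the list tests 11 lists lay higher in KO, although edgeR called 0 of their members over all genes. For the neutrophil and granulocyte precursor markers among them the expression filter favoured positive values, as in untreated cells. It may have done so for the macrophage markers too, of which 7 of 16 were tested. For cytokines and chemokines 23 of 26 genes had positive log2 fold changes with a median of 1.09, and 7 passed adjusted over the list alone. For immediate early genes 21 of 24 were positive with a median of 0.77, and 8 passed adjusted over the list alone. The median was 0.75 for cholesterol synthesis (5 of 27 adjusted over the list alone), 0.58 for MAPK feedback inhibitors (1 of 13) and 0.37 for NF-kB targets (4 of 21). It was 2.48 for neutrophil and granulocyte precursor markers (0 of 11 adjusted over the list alone), 0.75 for macrophage markers (1 of 7) and 0.53 for the integrated stress response (0 of 22). It was 0.49 for glycolysis (0 of 23), 0.41 for heat shock genes (0 of 12) and 0.30 for the oxidative stress response (0 of 20). These 11 lists had adjusted p between 1.1e-10 and 0.024, against adjusted p between 0.22 and 0.37 with an estimated correlation, so that 0 of the 11 held. The glycolysis and oxidative stress lists lost their calls with the mitochondrial share, 14.4% ± 17.4 in KO and 22.1% ± 17.4 in WT, as a covariate, and the oxidative stress list had adjusted p = 0.057 with the replicate number as a block. In edgeR, an adjusted p of 0.05 called 46 genes, 14 higher and 32 lower in KO. The count was 28 without KO 60 of number 4120, 183 with the replicate number as a block, and 224 with DESeq2, of which 98 were higher and 126 lower.

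The calls between KO and WT were shared across the levels. Of the 47 genes called at 0 and the 36 called at 20, 29 were called at both, all with the same sign, where independent lists would share 0.0986. The comparisons at 0 and 60 shared 33 genes and those at 20 and 60 shared 29, again all with the same sign. The 3 comparisons use different libraries, but a number's libraries of one genotype may come from one culture, so the overlap is not independent evidence. In total 64 genes were called at 1 or more levels and 26 at all 3, of which 7 were higher and 19 lower in KO, and 62 of the 64 had one sign at all levels. Among the 26, 9 are annotated as pseudogenes, whereas pseudogenes made up 6.65% of the genes tested. Of the 64 genes, 36 (56.25%) started within 5 Mb of another of them, in 13 chromosome segments of at least 2 genes. In 1000 random sets matched on expression the median share was 29.7% and the highest 53.1%. In 9 segments all genes had one sign over all levels and in 4 both signs occurred. Tulp3, Foxm1, Clec12b, Magohb and Styk1 were all lower in KO and lay between 128.32 and 131.35 Mb of chromosome 6. Tanc2, Kcnh6, Dcaf7 and Kpna2 were all higher and lay between 105.59 and 107 Mb of chromosome 11. None of the 64 lay within 20 Mb of Sirt6 or of Lyz2. Tulp3, Foxm1 and Magohb were singled out for their position after their values were seen.

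**Figure D2:**
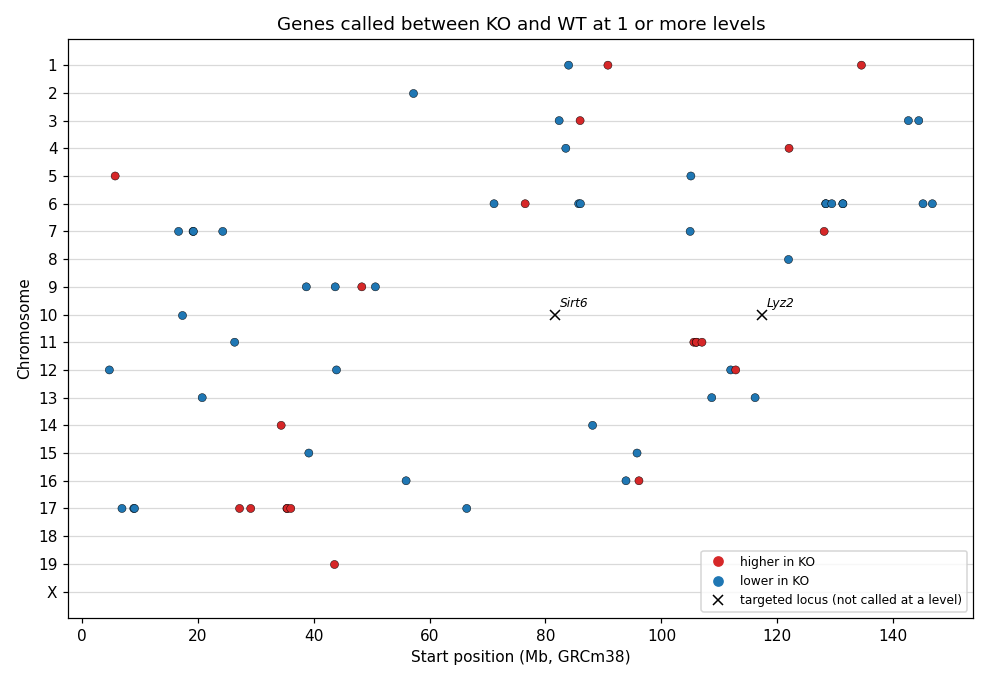
Start position in Mb (GRCm38) of the 64 genes called between KO and WT at 1 or more levels, one line per chromosome, with red points for genes higher and blue points for genes lower in KO. Crosses mark Sirt6 and Lyz2 on chromosome 10, and the 4 red points near 106 Mb of chromosome 11 are Tanc2, Kcnh6, Dcaf7 and Kpna2.

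Averaged over the 3 levels, more genes passed the test, with smaller differences. Kit, the stem cell factor receptor on which mast cells depend, rose from 1284 ± 233 CPM in WT to 2045 ± 210 CPM in KO (SD over n = 3 cultures). Tpsab1, a mast cell tryptase gene annotated as a transcribed pseudogene, rose from 781 ± 514 to 2173 ± 995 CPM. Itpr2, a calcium release channel gene downstream of FcεRI, fell from 483 ± 264 to 141 ± 35.3 CPM, and the platelet integrin gene Itga2b fell from 5046 ± 442 to 3155 ± 461 CPM. Col6a3 (6.29), Nxpe2 (6.16) and Kcnh6 (3.88) were again higher, and Gbp2b (−9.42), Gm42048 (−9.26), Gm9522 (−8.65), Gm10154 (−7.88), Clec12b (−7.12) and Gm5900 (−6.71) lower. Gm39813 had no count in KO and 5.08 ± 5.23 CPM in WT, at least 473-fold lower, and Gm46108, which overlaps Nectin1, fell by 6.50. Vill (12.7 ± 21.8 CPM in KO), Rpl29 (382 ± 436), Magi1 (22.6 ± 23.5) and Gm17669 (6.40 ± 6.93) were also called higher, with a spread between cultures above their mean. Arhgap31 was called at 6.33 ± 5.47 CPM in KO, and the value of Vill without number 414 was −1.16. Of the genes of cholesterol synthesis 9 of 27 rose, among them Hsd17b7 (1.73) and Scd1 (1.23), and 17 passed adjusted over the list alone. The list had adjusted p = 2.3e-09, against adjusted p = 0.36 with an estimated correlation. Of the neutrophil and granulocyte precursor markers 6 of 11 rose, among them Ly6g (6.55), Ltf (4.58), Lcn2 (3.39) and S100a9 (3.24), and 8 passed adjusted over the list alone. These markers stayed low, at 4.32 ± 3.26 CPM in KO for S100a9, and the expression filter favoured positive values, as in untreated cells. Their list had adjusted p = 2.9e-06, against adjusted p = 0.30 with an estimated correlation. Macrophage markers were called with a median of 0.53 (1 of 7 higher over all genes, Itgam, and 2 adjusted over the list alone), against adjusted p = 0.36 with an estimated correlation. The filter may favour positive values here too, as 7 of 16 markers were tested and Itgam was at 0.034 CPM in WT at 0. Glycolysis (median 0.42, 0 of 23 called either way), the integrated stress response (median 0.27, 1 of 22 either way) and heat shock genes (median 0.32, 1 of 12 either way) were called too, against adjusted p = 0.70 for each with an estimated correlation. The last 3 lists lost their calls with the mitochondrial share as a covariate. At an adjusted p of 0.05, edgeR called 1872 genes, 736 higher and 1136 lower in KO, and limma on TPM called 201 higher and 180 lower. With counts summed per culture 27 genes passed, 7 higher and 20 lower, and the ones named here or at the single levels were Add2, Styk1, Nectin1, Gbp2b, Col6a3, Nxpe2, Kcnh6, Kpna2, Clba1, Gm9008, Gm42048, Gm9522, Gm10154, Gm5900, Gm4705, Gm5586, Rpl34-ps1 and Rps3a3. The cholesterol, neutrophil and macrophage list members named here were not among them. Their calls over all levels thus count the libraries of a culture as separate samples. The mitochondrial share as a covariate gave 746 genes, 275 passed without the 5 libraries over 20%, and leaving out 1 library gave 1238 without KO 0 of 414, 1105 without KO 0 of 6110, 975 without KO 20 of 414, 1101 without KO 60 of 6110, 1112 without WT 0 of 4120, 1193 without WT 20 of 4120, 1059 without WT 60 of 414 and 3159 without WT 0 of 6110.

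The next comparisons asked how WT and KO cells responded at 20 and 60. In WT cells at 20, cytokine and immediate early transcripts rose steeply. Il13, a type 2 cytokine gene, rose from 0.354 ± 0.210 CPM at 0 to 143 ± 43.1 CPM at 20, and Tnf rose from 6.46 ± 3.71 to 717 ± 317 CPM (SD, n = 3). The chemokine genes Ccl3 (5.13) and Ccl4 (5.70), whose annotations overlap, and Il6 (4.61) rose as well. Ptgs2, the inducible cyclooxygenase gene, rose by 6.27 on the log2 scale, and the transcription factor genes Fos (5.45), Egr2 (5.24) and Nr4a1 (4.67) rose with Btg2 (4.72). Dusp1, a phosphatase gene that limits MAPK signalling, rose by 5.52, and Nfkbid, an atypical IκB gene, rose by 5.17. Of the cytokines and chemokines 13 of 26 rose (19 adjusted over the list alone) and of the immediate early genes 17 of 24 (21 adjusted over the list alone). Both lists held with an estimated correlation (adjusted p = 9.4e-05 for each). MAPK feedback inhibitors rose in 7 of 13 cases (7 adjusted over the list alone), among them Dusp5 (3.60), Dusp8 (from 0.684 to 5.41 CPM) and Spry1 (from 0.524 to 4.29 CPM), and NF-kB targets in 5 of 21 (8 adjusted over the list alone), among them Nfkbiz (3.69), Nfkbia (3.68) and Tnfaip3 (3.34). These lists held as well, with adjusted p = 0.0038 and adjusted p = 0.0029 with an estimated correlation. The other 6 list calls were oxidative stress (1 of 20 rose, Srxn1, and 2 adjusted over the list alone), heat shock (1 of 12 either way, Dnajb1), inhibitory receptors and negative regulators (2 of 30, Rgs1 and Rgs2, and 3 adjusted over the list alone), eicosanoid synthesis (1 of 16 either way, Ptgs2), glycolysis (0 of 23 either way) and cholesterol synthesis (0 of 27 either way). They were lost, with adjusted p between 0.17 and 0.64 with an estimated correlation, and the eicosanoid list was called upward although its median was −0.02. Map3k8, a kinase gene of the TLR4 list, rose by 4.42 and the activation marker gene Cd69 by 2.36, and Csf2 passed with 171 counts at 20 and 2 at 0. By edgeR at an adjusted p of 0.05, the test called 103 genes, all of them higher at 20. The mitochondrial share was 17.4% ± 14.3 at 20 and 22.6% ± 14.5 at 0. With the replicate number as a block the mast cell identity list was called upward as well (adjusted p = 0.046), with a median of 0.08 and 0 of 25 members called by edgeR over all genes or adjusted over the list alone. Without the block it had adjusted p = 0.20, and adjusted p = 0.68 with an estimated correlation. The count was 58 without WT 0 of number 4120, 47 without WT 0 of 414 and 64 without WT 20 of 414, 158 with the replicate number as a block (151 higher, 7 lower) and 200 with DESeq2 (182 higher, 18 lower). With the block in the compared groups alone it was 385 (294 higher, 91 lower), and with the culture as a random effect 201 (175 higher, 26 lower), so the absence of falls depends on the fit.

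In WT cells at 60, transcripts of 2 nuclear receptors, of Il13 and of Srxn1 were among those higher than at 0. Nr4a3, an orphan nuclear receptor gene, rose from 60.1 ± 44.5 to 627 ± 274 CPM, Nr4a2 from 62.5 ± 13.0 to 320 ± 176 CPM and Il13 from 0.354 ± 0.210 to 7.23 ± 7.28 CPM (SD, n = 3). Srxn1, which repairs oxidised peroxiredoxins, rose from 288 ± 93.1 to 1233 ± 479 CPM. Mst1r (3.44), Ptgs2 (3.11), Map3k8 (2.99), the sphingosine 1-phosphate receptor gene S1pr3 (2.98), LOC115489130 (2.94), Trib1 (2.70), Map2k3os (2.33), Nfkbid (2.30) and Cd33 (from 49.9 to 230 CPM) rose too. LOC115489130 overlaps Lamp2 and Map2k3os is named as an antisense transcript, so both values are uncertain. The 4 genes that fell were Sertad3 (−1.47), Zbtb5 (−1.14), Ccm2 (−0.98) and Bicra (−0.91). Over all genes 2 of 24 immediate early genes, 1 of 26 cytokines and chemokines, 1 of 21 NF-kB targets and 1 of 13 MAPK feedback inhibitors rose, whereas 12, 12, 10 and 8 passed adjusted over the list alone. These 4 lists had medians of 1.18, 1.39, 0.86 and 1.48 and adjusted p of at most 1.6e-10, against adjusted p = 0.073, 0.062, 0.062 and 0.098 with an estimated correlation. Cholesterol synthesis (0 of 27 called, 3 adjusted over the list alone), the integrated stress response (0 of 22 either way), oxidative stress (1 of 20, and 2 adjusted over the list alone) and heat shock (0 of 12, 6 higher and 1 lower adjusted over the list alone) were also called upward. They too were lost, with adjusted p between 0.17 and 0.29 with an estimated correlation. In edgeR, an adjusted p of 0.05 called 38 genes, 34 higher and 4 lower at 60, and the mitochondrial share was 22.1% ± 17.4 at 60. The count was 1 without WT 0 of number 414, 7 without WT 0 of 4120, 3 without WT 60 of 6110, 73 without WT 60 of 414, 225 with DESeq2, 4 (3 higher, 1 lower) with scaling by library size alone, and 0 without the 5 libraries over 20%.

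In KO cells at 20, Tnf rose from 2.87 ± 0.902 to 1021 ± 306 CPM, Il13 from 0.570 ± 0.204 to 134 ± 45.4 CPM and Fos from 9.46 ± 1.96 to 908 ± 279 CPM (SD, n = 3). Csf2, the GM-CSF gene, had no count in KO at 0 and 2.42 ± 2.05 CPM at 20, at least 79.7-fold higher. Ptgs2 (6.39), Egr2 (6.19), Dusp1 (5.96), Nfkbid (5.69), Ccl4 (5.52), Ccl3 (5.15), Ccl7 (5.13), Btg2 (4.95) and Map3k8 (4.80) rose as well. Of the immediate early genes 17 of 24 rose (21 adjusted over the list alone), of the cytokines and chemokines 12 of 26 (19 adjusted over the list alone), of the MAPK feedback inhibitors 6 of 13 (7 adjusted over the list alone) and of the NF-kB targets 5 of 21 (7 adjusted over the list alone). All 4 lists held, with adjusted p = 3.1e-05, 3.1e-05, 0.0020 and 0.0018 with an estimated correlation. Examples were Nr4a1 (4.59) among immediate early genes, Dusp5 (3.19), Dusp6 (3.15) and Spry1 (2.82) among MAPK feedback inhibitors, and Nfkbia (4.26), Nfkbiz (3.65) and Gadd45b (3.28) among NF-kB targets. The other 6 list calls were glycolysis (0 of 23 either way), inhibitory receptors and negative regulators (1 of 30, Rgs1, and 3 adjusted over the list alone), eicosanoid synthesis (1 of 16 either way, Ptgs2), oxidative stress (1 of 20 either way, Srxn1), the integrated stress response (0 of 22 either way) and heat shock (1 of 12 either way, Dnajb1). They were lost, with adjusted p between 0.14 and 0.76 with an estimated correlation. At an adjusted p of 0.05, edgeR called 77 genes, 76 higher and 1 lower at 20. The mitochondrial share was 6.32% ± 1.61 at 20 and 13.7% ± 11.9 at 0. With the replicate number as a block the list of neutrophil and granulocyte precursor markers was called upward as well (adjusted p = 0.039), with a median of 0.71 and 0 of 11 members called by edgeR over all genes or adjusted over the list alone. Without the block it had adjusted p = 0.34, and adjusted p = 0.76 with an estimated correlation. The count was 137 with DESeq2 and 47 without the 5 libraries over 20%, and no single left-out library moved it by over 1.5 times.

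In KO cells at 60, Nr4a3 rose from 30.9 ± 10.5 to 1246 ± 298 CPM, Srxn1 from 199 ± 22.3 to 1986 ± 444 CPM, Tnf from 2.87 ± 0.902 to 99.1 ± 24.0 CPM and Il13 from 0.570 ± 0.204 to 47.7 ± 21.2 CPM (SD, n = 3). Mst1r (6.78), the chemokine genes Ccl1 (5.53) and Ccl7 (5.26), Map3k8 (5.31), Rgs16 (5.24), Ptgs2 (5.12), the growth factor gene Hbegf (4.88), Atf3 (4.77) and Trib1 (4.74) rose as well. Cxcl2 and Csf2 had no count in KO at 0 and were at least 70.7-fold and 41.6-fold higher at 60. The named falls were 2900052L18Rik (−2.51), Gm39648 (−2.44), Gm7428 (−2.38), Gm46412 (−1.73), Zfp975 (−1.70), Gm31320 (−1.60), Rhebl1 (−1.55), Zbtb5 (−1.44), Tmtc3 (−1.39), Osbpl5 (−1.38), Zfp945 (−1.37) and Zfp157 (−1.35). Gm7428 and Gm31320 overlap each other and the mast cell protease gene Cpa3, Gm46412 overlaps Nup153 and Gm39648 overlaps Gm973, so these values are uncertain. Of the immediate early genes 12 of 24 rose (22 adjusted over the list alone), of the cytokines and chemokines 12 of 26 (19 adjusted over the list alone), of the NF-kB targets 10 of 21 (15 adjusted over the list alone) and of the MAPK feedback inhibitors 8 of 13 (9 higher and 1 lower adjusted over the list alone). Of the genes of the integrated stress response 7 of 22 rose (15 adjusted over the list alone), among them Chac1 (3.76), Sesn2 (1.53), Trib3 (from 72.5 to 205 CPM) and Mthfd2 (1.31). These 5 lists held, with adjusted p = 0.0090, 0.0065, 0.0086, 0.041 and 0.041 with an estimated correlation. Of the cholesterol genes 5 of 27 rose (7 adjusted over the list alone), among them Cyp51 (2.03), Msmo1 (1.77) and Hmgcs1 (1.68), and the list had adjusted p = 0.23 with an estimated correlation. Oxidative stress (3 of 20, Srxn1, Hmox1 and Slc7a11, and 5 adjusted over the list alone), heat shock (1 of 12, Dnajb1, and 8 adjusted over the list alone), inhibitory receptors (2 of 30, Rgs1 and Rabgef1, and 6 adjusted over the list alone) and eicosanoid synthesis (1 of 16 either way, Ptgs2) were called too. They were lost, with adjusted p between 0.14 and 0.22 with an estimated correlation. By edgeR at an adjusted p of 0.05, the test called 436 genes, 341 higher and 95 lower at 60, the mitochondrial share was 14.4% ± 17.4 at 60, and limma on TPM called 79 higher and 8 lower. The count was 184 without KO 0 of number 4120, 180 without KO 0 of 414, 235 without KO 60 of 4120, 256 without KO 60 of 6110, 1094 with the replicate number as a block (722 higher, 372 lower), 948 with DESeq2 (661 higher, 287 lower) and 105 without the 5 libraries over 20%. With the block in the compared groups alone it was 1784 (1037 higher, 747 lower), and with the culture as a random effect 1847 (1013 higher, 834 lower).

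**Figure D3:**
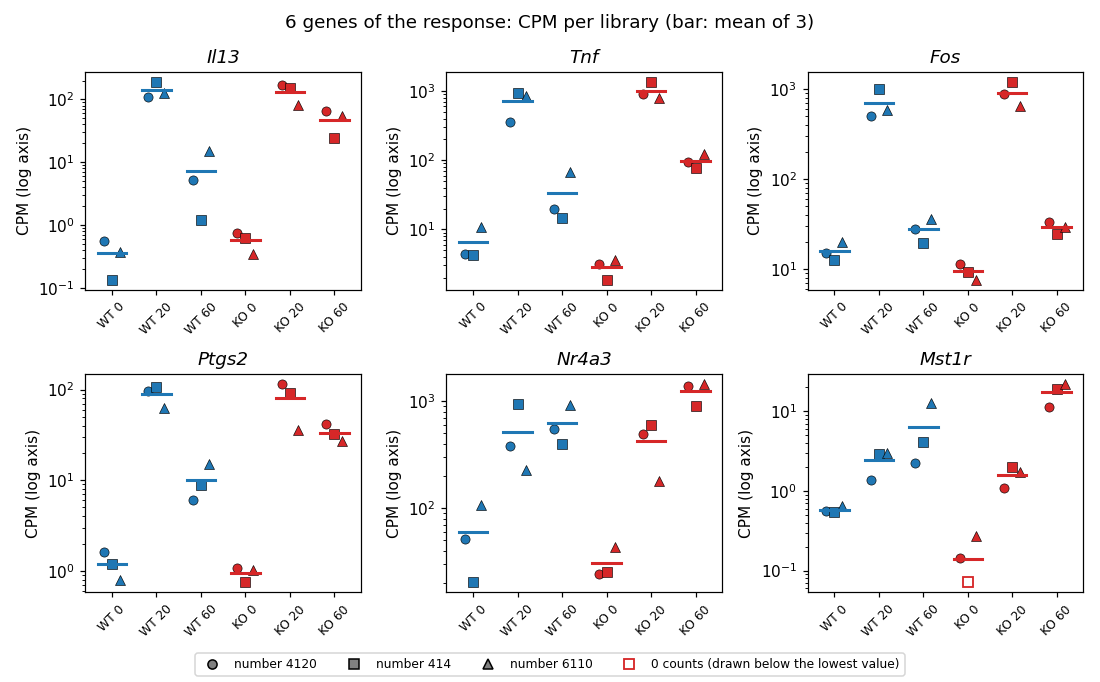
CPM per library on a log axis for 6 genes of the response, by genotype and level, with a horizontal bar at the mean of 3 libraries and the marker shape giving the library's number. Tnf and Fos lie highest at 20, at means of 717 and 693 CPM in WT and 1021 and 908 CPM in KO, and the open marker is the KO library of number 414 at 0, in which Mst1r had no count.

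The last comparison asked whether the response differed between KO and WT, by the interaction of genotype and level. At 20, Tagap1 had the smallest p, with a response 2.76 ± 0.40 (SE) higher in KO on the log2 scale and an edgeR adjusted p of 0.063. Tagap1, which has a paralog, Tagap, and is uncertain for that reason, was lower in KO at 0 (8.55 ± 1.32 against 54.0 ± 16.6 CPM, SD, n = 3), where it was called, and stood at 66.1 ± 18.3 against 61.5 ± 19.4 CPM at 20. At 60, the differences with the smallest p were those of Tagap1 (2.23), Got1 (1.11), Map3k8 (2.32), Ccl7 (2.72) and Egr2 (2.21), with edgeR adjusted p between 0.71 and 1. The other genes with the smallest p at 20 were Gm8752 (−2.46) and Gm38850 (−2.86), and Gm42090 and LOC115487209, which had no count in WT at 0 and are given no value for that reason. The edgeR test called 0 genes at 20 and 0 at 60, with 68 and 188 genes at an unadjusted p under 0.05. DESeq2 called 1 gene at 20 and 2 at 60, limma-voom called 0 and 0, and limma-voom with the culture as a random effect called 1 and 0. At 20, edgeR called 1 gene without KO 20 of number 4120, without WT 0 of 6110 or without WT 20 of 414. In the list tests 0 lists were called at 20 and 5 at 60, all with a larger rise in KO. The median difference was 1.41 over 26 cytokines and chemokines (23 positive, 4 adjusted over the list alone) and 0.92 over 24 immediate early genes (23 positive, 1 adjusted over the list alone). Of these 26 genes 4 had no count in at least one group at 0 or 60, and without them the median difference was 0.97. The median was 0.70 over 13 MAPK feedback inhibitors (9 positive), 0.55 over 21 NF-kB targets (16 positive) and 0.51 over 22 genes of the integrated stress response (21 positive), with 0 members passing either way. The 5 lists had adjusted p = 4.0e-19, 4.0e-19, 8.7e-05, 8.7e-08 and 4.4e-10 in this order, against adjusted p = 0.052, 0.12, 0.40, 0.13 and 0.15 with an estimated correlation, so that 0 of the 5 held.

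Of the 29 lists, 16 were called in none of the 10 comparisons without the replicate block. They were mast cell identity, FcεRI signalling, degranulation and calcium entry, the TLR4 pathway, interferon-stimulated genes, protein tyrosine phosphatases, sirtuins, DNA repair, ribosome biogenesis, cell cycle, sex-linked genes, and the markers of basophils, eosinophils, lymphocytes, dendritic cells, and erythroid cells and megakaryocytes. The lowest camera adjusted p among them without the block was 0.054, for FcεRI signalling in WT 20 against 0. With the block mast cell identity was called upward in WT 20 against 0, as given above. Of all 65 list calls 13 held with an estimated correlation, 4 in WT at 20, 4 in KO at 20 and 5 in KO at 60, and 0 of the 22 between KO and WT held. For KO against WT at 0, the median log2 fold change was 0.11 over 25 mast cell identity genes, 0.11 over 34 FcεRI signalling genes and 0.27 over 27 degranulation genes. Single members could pass, as Kit, Tpsab1 and Itpr2 did over all levels, although none of these 3 passed with counts summed per culture.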

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

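The tests with the mitochondrial share in this part were chosen after the result was seen. In the interaction of genotype and level at 60, 5 gene lists passed the test of a difference between the KO and WT responses, which is why they are described here. The median difference was 1.41 for cytokines and chemokines (0.97 without the 4 members that had no count in a group), 0.92 for immediate early genes, 0.70 for MAPK feedback inhibitors, 0.55 for NF-kB targets and 0.51 for the integrated stress response. Single genes did not pass: edgeR called 0, with 188 at an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0. None of the 5 lists passed with an estimated correlation (adjusted p = 0.052 to 0.40) or with fry (0.53 to 0.83).

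If one number carried the difference, its median over the 106 members would be near 0 in another number. The medians were 0.81, 0.77 and 0.48 in numbers 4120, 414 and 6110, so in these members no single number carried the difference. The lists were called on the same differences, however, which favours positive medians, so this is not independent evidence. With the mitochondrial share as a covariate 103% of the median difference was kept (0.63 before, 0.65 with it). Without the 5 libraries over 20% the median was 0.54, with a median SE per gene of 0.69. The members were chosen in these same libraries, which favours sizes that remain. Without the 5 libraries KO also kept lower shares at 0 and 60, and the WT response compared partly different numbers. These values thus do not decide whether RNA quality is the whole cause. A larger or more lasting response in KO stays open as a hypothesis, as does a difference between cultures. The difference in response also subtracts the values at 0, so lower values in KO at 0 would add to it. The members of a list move together, so the preset test may overstate the evidence. Other splits of the cultures called as many lists in 3 of 10 cases, the real one included, with 5 lists in the real split and 6 as the highest other. The 10 splits are too few for a share under 0.05.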

How the results depend on the processing

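The settings with the mitochondrial share were chosen after the data were seen; the others were planned, and the cause of a change was not tested. The edgeR counts below are given for KO against WT at 0, 20, 60 and over all levels, then WT 20, WT 60, KO 20 and KO 60, where they moved by over 1.5 times from 47, 36, 46, 1872, 103, 38, 77 and 436.

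An adjusted p under 0.01 gave 24, 23, 28 and 422, then WT 20 59, WT 60 7 and KO 60 177, and a 2-fold change gave 672 over all levels. DESeq2 gave 251, 119, 224 and 2977, then 200, 225, 137 and 948, and 1 and 2 for the responses at 20 and 60. Protein-coding genes alone gave 29, 19 and 29. The compared groups alone gave 14, 20 and 17, then WT 20 46, WT 60 0 and KO 60 202. The replicate block gave 208, 119, 183 and 3972, then WT 20 158, WT 60 206 and KO 60 1094, and within the compared groups 17, 23 and 119, then 385, 16 and 1784. The block with the mitochondrial share gave 290, 149 and 224, then WT 20 189, WT 60 525 and KO 60 1906. The share alone gave 746 over all levels, WT 60 71 and KO 60 694. Without the 5 libraries over 20% the counts were 22 at 0, 19 at 60, 275 over all levels, then 51, 0, 47 and 105. Library size alone gave 864 over all levels, WT 60 4 and KO 60 163. The culture as a random effect in limma-voom gave 129 over all levels, then 201, 445, 136 and 1847. TPM gave 381 over all levels, WT 20 59, WT 60 1 and KO 60 87, and FPKM gave 915, WT 60 3 and KO 60 195. Sums per culture gave 27, and 23 with the block. A mean of at least 1 CPM gave WT 60 63. The response difference at 20 had 1 gene with that filter, with no filter, with protein-coding genes alone and with the culture as a random effect.

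Leaving out whole numbers gave 20 to 39 genes at 0, 18 to 31 at 20, 15 to 55 at 60 and 255 to 1495 over all levels, then WT 20 22 to 83, WT 60 0 to 0, KO 20 23 to 64, KO 60 19 to 147 and 0 to 0 for the responses. Sirt6 ranged from −0.017 to 0.33 at 0, 0.10 to 0.41 at 20 and 0.08 to 0.17 at 60, and Vill over all levels from −1.16 (without number 414) to 9.9 (without number 6110). Leaving out single libraries gave 27 to 48 at 0, 22 to 31 at 20, 28 to 54 at 60 and 975 to 3159 over all levels, then WT 20 47 to 102, WT 60 1 to 73, KO 20 53 to 76, KO 60 180 to 366, and 0 to 1 and 0 to 0 for the responses at 20 and 60.

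Over 273 named results, gene by gene, 6079 values kept direction and side of the threshold, 1894 kept direction but no longer passed, 13 passed only in the alternative and 2 changed sign. Of 65 list calls, 13 passed with an estimated correlation, 25 with fry, 55 with the mitochondrial share, 59 without the 5 libraries and 64 with the block. The alternative for a file without counts was not run.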

Other observations

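The tests with the mitochondrial share were chosen after the result was seen, and the fit with the culture as a random effect, itself fixed in advance, was chosen as the test of the calls over all levels only then. All 6 libraries of number 414, of both genotypes, had Xist at 608 to 2316 CPM and Ddx3y at 0.166 CPM or less. The other 12 libraries had Xist at 1.62 CPM or less and Ddx3y at 16.3 to 84.3 CPM. This is the pattern of female cells in number 414 and of male cells in the others. Sex is balanced between the genotypes and is part of the difference between the numbers.

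The genes called between KO and WT at all 3 levels include many pseudogenes and sharp losses, and they cluster on chromosomes. Of the 26 genes, 38.5% had another within 5 Mb, against a median of 11.5% and a 95th percentile of 30.8% in random sets, and 12 of 1000 sets reached as much. Among the 15 protein-coding genes 40% had a neighbour, against a 95th percentile of 26.7%, and the 103 genes called in WT at 20 had 47.6%, below their 95th percentile of 54.4%. With the mitochondrial share as a covariate 107% of the median absolute log2 fold change was kept (4.93 before, 5.27 with it), and without the 5 libraries over 20% it was 4.85, with 50 of the 78 calls left as the median SE went from 0.52 to 0.57. This argues against RNA quality as the whole cause. A candidate explanation is chromosome segments of another strain that differ between the WT and KO mice. A direct effect of Sirt6 loss, which the counts do not show, stays open as well, and no genotypes were available to test either.

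The 1872 genes called over all levels rest on 9 libraries per genotype, which form 3 cultures each by the naming used here. The labels do not say whether the libraries of such a culture share their cells. With the culture as a random effect limma-voom called 129, against 1773 without it, and sums per culture gave 27, so most of the 1872 calls may reflect differences between cultures counted as separate samples. With the mitochondrial share as a covariate 746 genes passed, 622 of them among the 1872, and the median absolute log2 fold change of the 1872 went from 0.80 to 0.66, so that 82.8% of the size remained, with a median SE of 0.19 before and 0.20 with it. Without the 5 libraries with a share over 20% only 275 passed, 258 of them among the 1872, and the median size was 0.67 with a median SE of 0.22, as smaller differences met a larger error with fewer libraries. Most single calls thus ended under either setting. The 1872 genes were chosen in these same libraries, which favours sizes that remain. Without the 5 libraries, KO also kept lower shares at 0 (10.1% and 4.07% against 17.7% and 11.1% in WT). At 60 it was the same (4.45% and 4.27% against 8.80% and 15.7%), while at 20 the ranges overlapped. The remaining sizes thus do not decide whether RNA quality is the whole cause. A part of the differences may come from it, and the calls themselves are not robust to it. An effect of genotype on the smaller differences stays open.

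Splits of the libraries into groups of the same sizes were counted for each comparison, and 10 splits are too few for a share under 0.05. As many genes as in the real split were called in 1 of 10 splits for KO against WT at 0 (47 genes, highest other 0), 20 (36, 0) and 60 (46, 0), for WT 20 (103, 0), for KO 20 (77, 0) and for KO 60 (436, 0). For WT 60 it was 2 of 10 (38, highest other 881). That other split set WT 0 of number 6110 with WT 60 of 4120 and 6110 against the rest, which parts low from high mitochondrial shares and points to a structure of the samples. Over all levels with whole cultures it was 2 of 10 (1872, highest other 3511), where the other split set KO and WT of 4120 with WT of 414 against the rest. With single libraries exchanged within levels it was 1 of 100 (1872, highest other 566), but libraries of a culture are not exchangeable, so this does not exclude chance. For the differences in response it was 10 of 10 at 20 and 10 of 10 at 60 (0, highest other 0).

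For gene lists, as many calls were found in 9 of 10 splits for KO against WT at 0 (2 lists, highest other 8), 6 of 10 at 20 (3, 10), 2 of 10 at 60 (11, 13) and 4 of 10 over all levels (6, 11). It was 3 of 10 for WT 20 (10, 12), 5 of 10 for WT 60 (8, 13), 2 of 10 for KO 20 (10, 10), 4 of 10 for KO 60 (10, 12) and 10 of 10 for the difference in response at 20 (0, 7).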
